A study of Homo sapiens with 9 samples.

How the data were processed

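RNA was measured in MCF-7 cells, an established human breast adenocarcinoma line that expresses the oestrogen receptor, after 48 hours with resveratrol, a plant stilbenoid polyphenol, or with ethanol vehicle. The labels give 3 groups of 3 arrays each, namely control, 150 µM and 250 µM resveratrol. Per the labels, 9 plates were grown per condition, and RNA of 3 plates was pooled for each array, so that the arrays of a group came from separate plates. Whether these plates were grown in separate experiments is not given in the sources used here, and p-values then measure only the spread between such pools. The labels disagree on some points. Sample titles give the doses in mM, while the protocol and the design text give µM, which is used here. The protocol gives the control vehicle as 0.03% ethanol, and the source name gives 0.3%. The protocol also gives 0.3% ethanol for the 250 µM cultures and 0.03% for the others, so dose and vehicle may change together at 250 µM.

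Per the labels, 300 ng of RNA per array was hybridised to Affymetrix human gene arrays of the whole-transcript type, in which probes spread along a gene are summarised into 1 value. Per the submitters' processing notes, the deposited log2 values were made with RMA, a method that corrects background, normalizes quantiles across arrays and summarises probes. The same notes name Partek software, and no version or test is given in the sources used here. The deposited table held 28869 rows, with log2 values from 1.79 to 14.67 and array medians from 5.47 to 5.66. No count or depth underlies an array value, and the number of arrays limits the precision.

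Rows were named through the platform's probe annotation. Exactly 1 gene symbol was given for 19310 rows, covering 18377 genes, and these were tested. Several symbols were given for 1752 rows and none for 7807, and these rows were left out of the comparisons. Of the tested rows, 19279 had a gene identifier found in NCBI's RefSeq gene table for GRCh38.p14, used for names only. A genome build for the array is not given in the sources used here, so no coordinates are printed. More than 1 tested row was present for 685 genes, and 329 tested rows had values identical to another row. Counts below are counts of rows, called genes for short. In gene list tests, the row with the highest mean over all arrays stood for a gene. Rows of a gene called in opposite directions were found for 1 gene at 150 µM, 10 genes at 250 µM and none in the comparison of the doses.

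Each row was fitted with limma (version 3.58.1, in R 4.3.3) on the deposited log2 values, with a mean per group over all 9 arrays, 6 residual degrees of freedom and moderated variances from eBayes, whose prior had 4.82 degrees of freedom. SEs come from this fit and pool the spread within all 3 groups. Where the 250 µM arrays differed, this widens SEs and raises p-values at 150 µM against control too. P-values were adjusted by Benjamini-Hochberg within a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were 3 in number, 150 µM against control, 250 µM against control and 250 µM against 150 µM, together with an F-test of any difference among the 3 groups. Gene lists, 36 in number, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The repair lists were chosen knowing that the series concerns lowered expression of DNA repair genes. Lists were tested with limma's camera, which compares a list's members with all other genes at a preset inter-gene correlation of 0.01, and again with a correlation estimated from the arrays. The estimate used the spread within groups over all 9 arrays, so that each list had a single value for all 3 comparisons. Differences among the 250 µM arrays thus enter the list p-values with an estimated correlation at 150 µM too. All list p-values were adjusted over the 36 lists.

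The rule for named genes took, per comparison, the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, and for the 6 called lists with the smallest camera p the 2 members with the largest change in the list's direction. It also took, in both comparisons against control, a fixed panel of MLH1, MSH2, MSH6, PMS2, BRCA1, BRCA2, RAD51, CDKN1A, CCND1, ESR1, CYP1A1 and SIRT1. MLH1, MSH2, BRCA2 and RAD51 had no row with a single gene symbol and were not analysed here. Other list members named as examples were chosen after their values were seen.

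The fit was tested on simulated arrays drawn from the real control means and the fitted spreads for 19310 rows, with known changes in some rows and small shifts of the p53 and mitosis lists. For 150 µM against control, 67 of 67 rows changed by 2 log2 units, 64 of 67 changed by 1 and 16 of 66 changed by 0.5 were recovered, with 8 of 19043 unchanged rows called. For 250 µM against control, 67 of 67, 63 of 67 and 19 of 66 were recovered, with 6 unchanged rows called. Both shifted lists and no other list were called in each, and between the simulated doses, which did not differ, 0 rows and 0 lists were called. The simulated rows were drawn independently of each other and with the same spread in every group. The simulation therefore does not test list calls among correlated genes, nor calls where the 250 µM arrays varied more than the others.

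Alternatives were quantile normalization of the deposited values again, centring arrays on their medians, keeping the brighter rows only, testing all rows, intensity-trended robust variances (statmod 1.5.0), array weights, fitting only the groups compared, the replicate number as a block, and leaving out each array in turn. For lists they were an estimated correlation, ranks in place of moderated statistics, and the mean of all rows of a gene. Spearman's correlation was the alternative for the dose comparison. The array weight was 0.141 for 250 µM array 1 and from 0.718 to 3.58 for the others. Array weights therefore come near leaving that array out and are not separate evidence from it. Leaving out 250 µM arrays 2 and 3 together, whose signal range was narrower, was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, in Python 3.11.15.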

Results

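Gene expression was profiled in MCF-7 cells after 48 hours of culture with 150 µM or 250 µM resveratrol or with vehicle, on 3 arrays per group, each carrying RNA pooled from 3 plates. The study asked how resveratrol changes expression in these cells, DNA repair genes in particular. Within the control group, log2 values of all rows, tested or not, correlated between arrays at 0.994 to 0.996, and within the 150 µM group at 0.993 to 0.994 (Pearson's r across rows, which are not independent replicates). The 250 µM arrays were less alike. The first of them correlated at 0.973, on average, with the other 250 µM arrays and at 0.989 with the 150 µM arrays, whereas 250 µM arrays 2 and 3 correlated with the 150 µM arrays at 0.971 and 0.970. 250 µM arrays 2 and 3 also had a narrower spread of log2 values (SD 1.99 and 2.02) than the other arrays (SD 2.07 to 2.19). With the tested rows divided by brightness into 4 equal parts, the dimmest part lay 0.21 and 0.20 log2 units above the control mean in the median on these arrays, and the brightest part had shifts of -0.27 and -0.22.

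At 150 µM, genes of cell division fell. All 39 measured genes of the mitosis list were lower than in control cells (39 adjusted over the list alone), with a median log2 fold change of -2.76 and an adjusted p of 1.08e-44 by limma's camera. PLK1, a kinase that drives mitotic entry, fell from a log2 signal of 10.14 ± 0.02 to 6.16 ± 0.11 (SD, n = 3), 15.8-fold lower. KIF20A, a kinesin of the central spindle, was lower as well, with a log2 fold change of -3.91 ± 0.25 (SE). Of 44 DNA replication genes, 39 fell (42 adjusted over the list alone), with a median of -1.28 and an adjusted p of 2.91e-32. Among them were ORC1, a subunit of the origin recognition complex (-2.83 ± 0.17), and POLE2, a subunit of DNA polymerase epsilon (-2.41 ± 0.11). Replication-dependent histone genes fell as well, 29 of 33 with 1 rising (29 and 1 adjusted over the list alone), with a median of -1.66 and an adjusted p of 4.99e-22 (adjusted p = 0.110 with an estimated correlation, so that the call was lost). H2BC14 showed the largest fall among the tested genes, -5.14 ± 0.19 or 35.4-fold, and H1-5 fell by 3.82 ± 0.26. Histone genes have near-identical copies, and probes for them can read more than a single gene. Among the G1/S regulators, 12 of 17 fell (12 adjusted over the list alone), with an adjusted p of 9.24e-11. The mitosis (adjusted p = 0.0389), DNA replication (0.0109) and G1/S (0.0292) calls held with an estimated correlation.

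Over the 8 DNA repair lists together, 56 of 128 measured genes fell at 150 µM, 9 rose and 63 did not pass the test, with a median of -0.40. In homologous recombination, the copying of an intact template to mend breaks, 17 of 24 genes fell and none rose (18 adjusted over the list alone), with a median of -0.92 and an adjusted p of 3.97e-12. BRCA1 went from 7.66 ± 0.12 to 5.46 ± 0.06 (SD, n = 3), 4.58-fold lower, with an adjusted p of 4.55e-06 from limma. The BLM helicase fell by 2.26 and XRCC2, a RAD51 paralogue, by 2.09. In mismatch repair, 4 of 6 measured genes fell (4 adjusted over the list alone), with a median of -0.42 and an adjusted p of 0.00276 (adjusted p = 0.121 with an estimated correlation, so that the call was lost). MSH6, a mismatch recognition subunit, fell by 0.73 ± 0.12 (SE), to 1.66-fold lower, and EXO1, the exonuclease of the pathway, fell by 1.88. PMS2 was lower by a margin near the threshold (log2 fold change -0.36 ± 0.12, adjusted p = 0.0449). Its call was lost in 8 of the alternatives, among them quantile normalization and omission of control array 1 or 2 or of any 150 µM array, with values from -0.45 to -0.29 and adjusted p up to 0.172. PMS2 also has near-identical pseudogene copies.

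Of the other repair lists at 150 µM, 8 of 14 Fanconi anaemia genes fell (8 adjusted over the list alone; adjusted p = 3.82e-06, and adjusted p = 0.0566 with an estimated correlation), with FANCI, a core member of the pathway's activated complex, at -1.80. Among 17 DNA damage checkpoint genes, 9 fell (11 adjusted over the list alone; adjusted p = 2.78e-07), and CHEK1, the checkpoint kinase, was at -2.41. Base excision repair genes fell in 9 of 21 cases and rose in 3 (10 and 3 adjusted over the list alone; adjusted p = 0.00241, and adjusted p = 0.110 with an estimated correlation), with the uracil glycosylase UNG at -1.79. Non-homologous end joining, with 4 of 12 fallen (5 adjusted over the list alone), was called at an adjusted p of 0.0494 (adjusted p = 0.250 with an estimated correlation). The call was also lost with quantile normalization (0.0625), with brighter rows only (0.184), with the mean of all rows of a gene (0.0504) and without control array 2 (0.0842) or 150 µM array 1 (0.0867). Translesion synthesis was not called (4 of 14 fell and 2 rose, adjusted p = 0.102). Nucleotide excision repair was not called either (adjusted p = 0.428). It had 4 of 20 genes higher and 1 lower, and its median (-0.01) and mean (0.10) differed in sign. The damage sensors DDB2 and XPC, both p53 targets, rose by 1.17 and 1.03. The homologous recombination (adjusted p = 0.0109) and checkpoint (0.0436) calls held with an estimated correlation, and the other repair calls were lost.

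Of 27 p53 targets, 26 rose at 150 µM and none fell (27 adjusted over the list alone), with a median of 1.17 and an adjusted p of 5.96e-25. GDF15, a secreted stress-induced cytokine, was raised 18.9-fold (4.24 ± 0.36, SE), PLK3 rose by 2.83 ± 0.17, and CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 8.22 ± 0.11 to 10.37 ± 0.08 (SD, n = 3). Immediate early genes rose in 16 of 17 cases, with 1 fall (16 and 1 adjusted over the list alone; adjusted p = 7.25e-13), led by ATF3 (2.75 ± 0.17) and DUSP1 (2.23 ± 0.17). NRF2 targets, the genes of the antioxidant response, rose in 14 of 19 cases (15 adjusted over the list alone; adjusted p = 1.59e-09, and adjusted p = 0.163 with an estimated correlation), with SRXN1 at 2.26 and SLC7A11, the cystine importer, at 2.46. ATF4 stress response genes rose in 16 of 28 cases (17 adjusted over the list alone; adjusted p = 6.04e-09), autophagy and lysosome genes in 14 of 20 with 1 fall (15 and 1 adjusted over the list alone; adjusted p = 4.31e-08), and endoplasmic reticulum chaperones in 11 of 18 (11 adjusted over the list alone; adjusted p = 3.20e-06, and adjusted p = 0.0566 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 19 cases and fell in 1 (13 and 2 adjusted over the list alone; adjusted p = 4.72e-05, and adjusted p = 0.188 with an estimated correlation). Glycolysis and hypoxia genes rose in 8 of 21 cases and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.0143, and adjusted p = 0.0877 with an estimated correlation), with the aldolase ALDOC at 2.69. The calls of p53 targets, ATF4 genes and autophagy (adjusted p = 0.0109 each) and of immediate early genes (0.0389) held with an estimated correlation, and the others in this paragraph were lost. For NRF2 targets the estimate was 0.553, which includes the spread among the 250 µM arrays. The list's means on the 150 µM arrays were 0.96, 0.93 and 1.00.

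Of 25 interferon response genes measured at 150 µM, 23 fell and 1, IRF1, rose (23 and 1 adjusted over the list alone), with a median of -1.64 and an adjusted p of 7.02e-13 (adjusted p = 0.143 with an estimated correlation, so that the call was lost). IFI44L fell by 4.20 ± 0.49 (SE), 18.3-fold, and IFIT1, an RNA-binding antiviral protein, had a log2 fold change of -3.91 ± 0.50. These SEs mostly reflect the 250 µM arrays, as the SD of IFI44L was 0.07 in control cells, 0.08 at 150 µM and 1.38 at 250 µM. The estimated correlation of the list, 0.558, likewise includes the spread among the 250 µM arrays. On the 150 µM arrays the list's means were -1.78, -1.81 and -1.82. Genes of mRNA splicing (16 of 24, 19 adjusted over the list alone; adjusted p = 4.51e-10) and ribosome biogenesis (11 of 21, 14 adjusted over the list alone; adjusted p = 5.00e-08, and adjusted p = 0.110 with an estimated correlation) also fell. A smaller fall was called for oxidative phosphorylation (8 of 26 fell and 1 rose, 8 and 1 adjusted over the list alone; adjusted p = 0.0184, and adjusted p = 0.188 with an estimated correlation). Heat shock proteins were called lower as well (5 of 10, 5 with 1 rise adjusted over the list alone; adjusted p = 0.0494, and adjusted p = 0.406 with an estimated correlation), as were luminal epithelial markers (4 of 14 fell and 2 rose, 4 and 2 adjusted over the list alone; adjusted p = 0.0494, and adjusted p = 0.350 with an estimated correlation). ESR1, which encodes the oestrogen receptor and is a luminal marker, fell by 1.75 ± 0.13, to 3.36-fold lower. Of these lists, only the splicing call held with an estimated correlation (adjusted p = 0.0303). The heat shock and luminal calls were each lost in 11 other alternatives, including omission of control array 2 or 150 µM array 1 (adjusted p up to 0.113 and 0.118), the glycolysis call with brighter rows only (0.0636) and that of oxidative phosphorylation without control array 2 (0.0514).

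The remaining lists were not called at 150 µM. The adjusted p was 0.428 for oestrogen receptor targets and for aryl hydrocarbon receptor targets, 0.306 for fatty acid synthesis, 0.640 for metallothioneins, 0.0822 for cytosolic ribosomal proteins and for sirtuins, 0.120 for apoptosis regulators, 0.601 for drug conjugation and efflux, 0.0974 for basal and mesenchymal markers and 0.806 for stromal, endothelial and leukocyte markers. Cytosolic ribosomal proteins were called up with trended variances (0.0403) and with ranks (0.0313). CYP1A1, the classic aryl hydrocarbon receptor target, had a log2 fold change of -0.73 ± 0.12 (SE), but its log2 signal of 5.16 in control cells and 4.42 at 150 µM lay below the median of all rows on every array (5.47 to 5.66), and the row was not shown to be above background. The deacetylase SIRT1 rose by 0.48 ± 0.10. CCND1, which encodes cyclin D1, had a log2 fold change of -0.19 ± 0.16 (adjusted p = 0.498). Other large rises were those of RND1, a Rho family GTPase (4.26 ± 0.27, 19.1-fold), the ammonia transporter RHCG (4.11 ± 0.53), the cytokine IL18 (3.33 ± 0.13), HCAR3 (3.27 ± 0.51) and GPR50 (3.11 ± 0.18). Background signal limits folds where a mean lay below the median of all rows on every array. In control cells this held for RHCG, IL18, GPR50 and ATF3, and at 150 µM for H2BC14, KIF20A, ORC1, POLE2 (4.23) and BRCA1 (5.46). In total 4437 of 19310 genes were called, 2042 higher and 2395 lower, and 465 and 632 of them changed at least 2-fold. Centring arrays on their medians turned the majority, with 2288 higher and 2139 lower. Groups did not overlap for 45.5% of genes, where chance gives 10%. The count was 7362 with array weights and 6799 when only these groups were fitted. Of the 36 lists, 24 were called, 8 up and 16 down, and 10 with an estimated correlation.

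**Figure D1:**
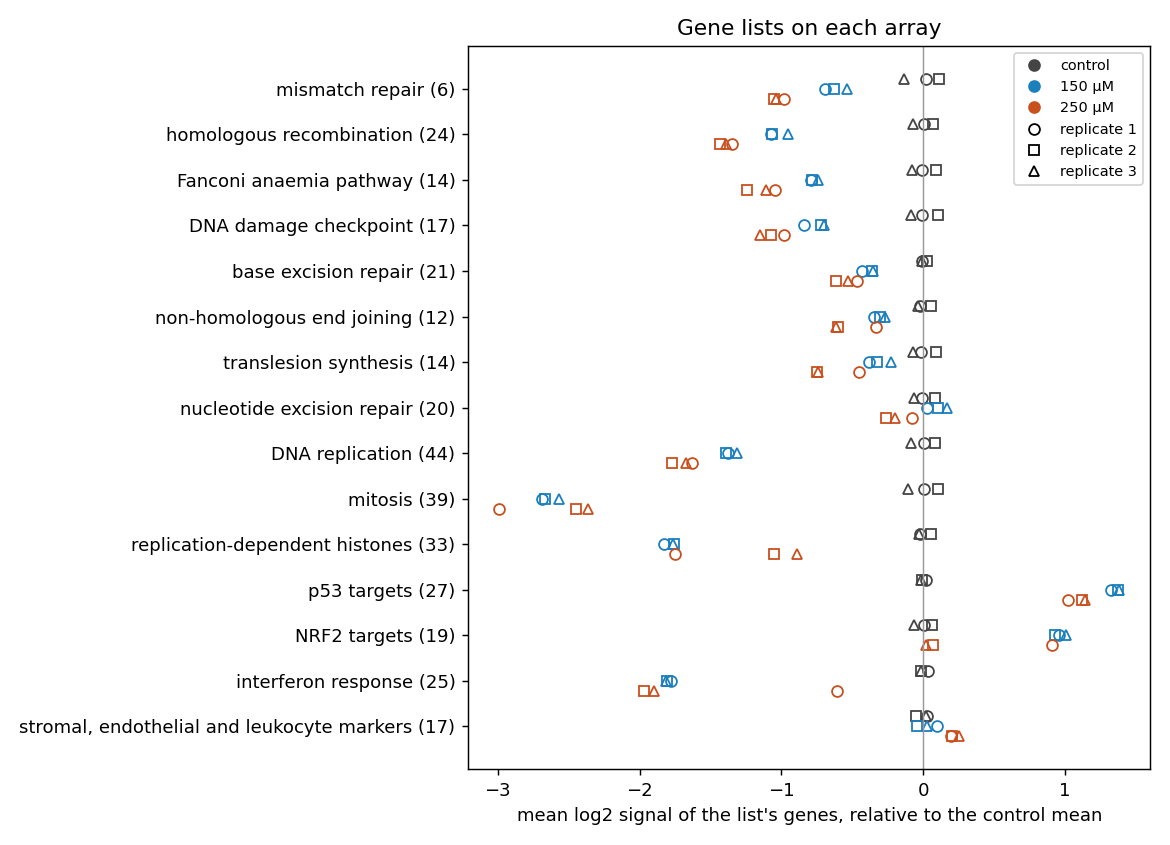
Mean log2 signal of 15 gene lists on each of the 9 arrays, relative to the control mean, with colour for the group, symbol for the replicate number and the number of measured genes in parentheses. Mitosis genes lie between -2.99 and -2.37 on all treated arrays, while NRF2 targets lie at 0.91 on the first 250 µM array and at 0.07 and 0.02 on the other 250 µM arrays.

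At 250 µM mitosis genes fell in 39 of 39 cases (39 adjusted over the list alone), with a median of -2.75 and an adjusted p of 6.37e-31 (adjusted p = 0.0693 with an estimated correlation, so that the call was lost). ASPM, a spindle pole protein, went from 8.94 ± 0.08 to 4.93 ± 0.13 (SD, n = 3), 16.1-fold lower, and DLGAP5, NDC80 and KIF11, which act in the spindle and the kinetochore, fell, with log2 fold changes of -3.81 ± 0.26, -3.78 ± 0.15 and -3.59 ± 0.13 (SE). DTL, a substrate receptor of a replication-coupled ubiquitin ligase, fell by 3.81 ± 0.14. Of 44 DNA replication genes, 43 fell (43 adjusted over the list alone), with a median of -1.64 and an adjusted p of 1.34e-28. GINS1 and CDC45, parts of the replicative helicase, were at -3.01 ± 0.14 and -2.77 ± 0.12. Histone genes fell in 22 of 33 cases (22 with 1 rise adjusted over the list alone; adjusted p = 1.06e-09, and adjusted p = 0.245 with an estimated correlation), with H2BC14 at -4.04 ± 0.19. G1/S regulators fell in 14 of 17 cases (14 adjusted over the list alone; adjusted p = 4.16e-10), with E2F8 at -2.77 ± 0.11 and SKP2 at -2.23 ± 0.15. The mean of the histone list was -1.75 on the first 250 µM array and -1.05 and -0.89 on arrays 2 and 3, which had the narrower signal range. The DNA replication (adjusted p = 0.0374) and G1/S (0.0488) calls held with an estimated correlation.

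Over the 8 repair lists, 85 of 128 genes fell at 250 µM, 7 rose and 36 did not pass, with a median of -0.69. Over all genes tested, 4365 fell at 250 µM and 2395 at 150 µM. All 6 measured mismatch repair genes fell (6 adjusted over the list alone), with a median of -0.62 and an adjusted p of 3.85e-04 (adjusted p = 0.0881 with an estimated correlation, so that the call was lost). MSH6 went from 8.62 ± 0.08 to 7.74 ± 0.16 (SD, n = 3), 1.84-fold lower. PMS2 fell by 0.49 ± 0.12 (SE, adjusted p = 0.00662), a call lost only with quantile normalization, at -0.28 and an adjusted p of 0.0880. EXO1 was at -3.09 and MSH3 at -0.59. In homologous recombination 20 of 24 genes fell and RAD52 rose (21 and 1 adjusted over the list alone), with a median of -1.42 and an adjusted p of 2.84e-11 (adjusted p = 0.0372 with an estimated correlation). The median was -0.93 among brighter rows. BRCA1 fell to 5.03 ± 0.37 (SD, n = 3), 6.18-fold below control, RAD51AP1 was at -2.98 ± 0.17 (SE) and the resolvase GEN1 at -2.78 ± 0.29. A fall was also called in the Fanconi anaemia pathway (11 of 14, 11 adjusted over the list alone; adjusted p = 3.34e-07, and adjusted p = 0.0546 with an estimated correlation) and in the checkpoint (13 of 17, 14 adjusted over the list alone; adjusted p = 1.36e-07, and adjusted p = 0.0546 with an estimated correlation). Base excision repair was called lower (11 of 21 with 1 rise, 11 and 2 adjusted over the list alone; adjusted p = 5.56e-04, and adjusted p = 0.0881 with an estimated correlation). Translesion synthesis (9 of 14 with 2 rises, 10 and 2 adjusted over the list alone; adjusted p = 0.00354, and adjusted p = 0.219 with an estimated correlation) and end joining (8 of 12 with 2 rises, 8 and 3 adjusted over the list alone; adjusted p = 0.0272, and adjusted p = 0.225 with an estimated correlation) were called lower too. The end joining call was lost with quantile normalization (0.0618), ranks (0.0580) or brighter rows only (0.410), and that of translesion synthesis with brighter rows only (0.263). The median of translesion synthesis was -0.28 without 250 µM arrays 2 and 3. Nucleotide excision repair was not called (7 of 20 fell and 1 rose, adjusted p = 0.251).

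**Figure D2:**
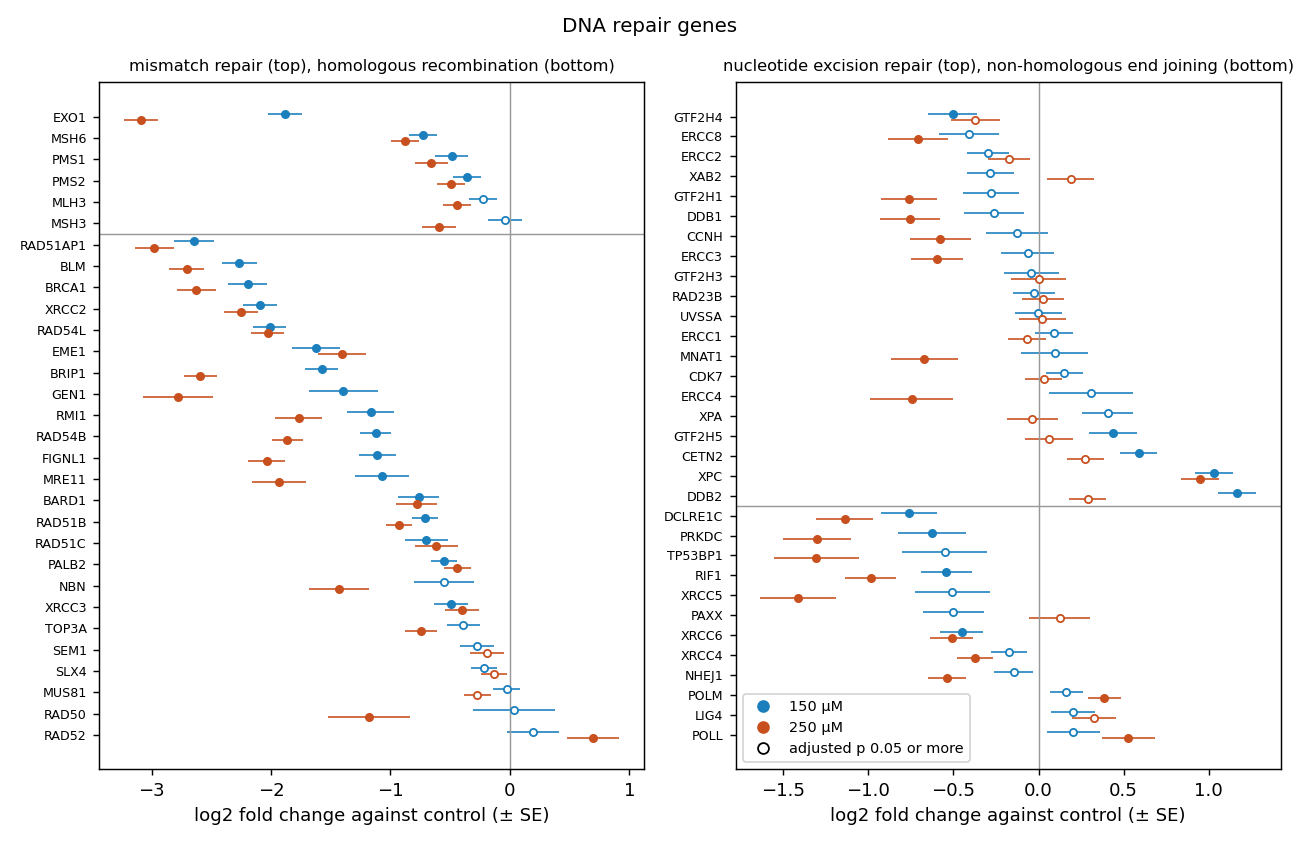
Log2 fold change against control (± SE, 3 arrays per group) of the measured genes of 4 repair lists at 150 µM and 250 µM, with open circles where the adjusted p was 0.05 or more. Homologous recombination genes lie mostly left of 0 (medians -0.92 and -1.42), and nucleotide excision repair genes lie on either side of it (medians -0.01 and -0.05).

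At 250 µM, 22 of 27 p53 targets rose and none fell (23 adjusted over the list alone), with a median of 0.82 and an adjusted p of 4.73e-12. GDF15 was 9.59-fold higher (3.26 ± 0.36, SE), but its log2 signal was 12.09 on 250 µM array 1 and 10.41 and 10.37 on the others. Its log2 fold change was 2.70 without array 1 and 4.39 without arrays 2 and 3. PLK3 rose by 2.91 ± 0.17 and CDKN1A by 2.22 ± 0.11. Immediate early genes rose in 15 of 17 cases with 1 fall (15 and 1 adjusted over the list alone; adjusted p = 1.06e-09, and adjusted p = 0.0655 with an estimated correlation), with ATF3 at 3.13 ± 0.17 and DUSP1 at 2.90 ± 0.17. ATF4 stress response genes rose in 13 of 28 cases and fell in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.00121, and adjusted p = 0.0655 with an estimated correlation), and DDIT3, which encodes the stress factor CHOP, rose by 3.22 ± 0.28. Endoplasmic reticulum chaperones rose in 12 of 18 cases with 1 fall (13 and 1 adjusted over the list alone; adjusted p = 2.53e-04, and adjusted p = 0.101 with an estimated correlation), among them HSPA5, the main chaperone of that compartment, at 1.32. Autophagy and lysosome genes rose in 14 of 20 cases with 1 fall (15 and 1 adjusted over the list alone; adjusted p = 2.55e-04, and adjusted p = 0.0546 with an estimated correlation). Cholesterol synthesis genes rose in 9 of 19 cases with 3 falls (11 and 3 adjusted over the list alone; adjusted p = 0.0312, and adjusted p = 0.444 with an estimated correlation), a call lost without 250 µM array 3 (0.0659) and without arrays 2 and 3 (0.275). NRF2 targets rose in 7 of 19 cases and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.0232, and adjusted p = 0.544 with an estimated correlation). This call was lost with ranks (0.0593) and without 250 µM array 1, where the adjusted p was 0.545 and the median 0.038. It was also lost with array weights (0.289), which gave 250 µM array 1 little weight (0.141). The list's mean was 0.91 on that array and 0.07 and 0.02 on the other 250 µM arrays. Its median of 0.24 moved to 0.42, 0.45 and 0.70 without array 2, array 3 and both, and to 0.39 with quantile normalization, where that of ATF4 genes moved from 0.34 to 0.54. Of the lists in this paragraph, only the call of p53 targets held with an estimated correlation (adjusted p = 0.0384).

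Interferon genes fell in 22 of 25 cases at 250 µM and 2, IRF1 and IRF7, rose (23 and 2 adjusted over the list alone; adjusted p = 2.33e-07, and adjusted p = 0.245 with an estimated correlation), with a median of -1.43. The list's mean was -0.61 on 250 µM array 1 and -1.97 and -1.90 on the others, and its median was -0.70 without the latter. Splicing genes fell in 20 of 24 cases (20 adjusted over the list alone; adjusted p = 1.47e-07, and adjusted p = 0.0546 with an estimated correlation), and ribosome biogenesis genes in 15 of 21 (17 adjusted over the list alone; adjusted p = 1.23e-06, and adjusted p = 0.141 with an estimated correlation). Oxidative phosphorylation genes fell in 13 of 26 cases with 1 rise (13 and 1 adjusted over the list alone; adjusted p = 0.00275, and adjusted p = 0.138 with an estimated correlation) and heat shock proteins in 6 of 10 with 1 rise (6 and 1 adjusted over the list alone; adjusted p = 0.0259, and adjusted p = 0.330 with an estimated correlation). The last pair of calls was lost with quantile normalization (0.0991 and 0.0761) and with brighter rows only (0.138 and 0.202), and that of heat shock proteins without 250 µM arrays 2 and 3 (0.130). Luminal markers fell in 7 of 14 cases (7 adjusted over the list alone; adjusted p = 0.00116, and adjusted p = 0.160 with an estimated correlation), with ESR1 at -2.13 ± 0.13 (SE), 4.36-fold lower. Oestrogen receptor targets fell in 12 of 24 cases and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.330 with an estimated correlation), and CCND1 was at -0.81 ± 0.16, and at -0.37 without 250 µM arrays 2 and 3. Sirtuins rose in 3 of 7 cases (5 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.225 with an estimated correlation), with SIRT1 at 0.69 ± 0.10. Without 250 µM arrays 2 and 3 the calls of oestrogen receptor targets (0.0653) and sirtuins (0.0809) were lost, and with brighter rows only that of oestrogen receptor targets (0.118). With quantile normalization the medians of oestrogen receptor targets and luminal markers moved from -0.35 to -0.17 and from -0.32 to -0.20.

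Markers of stromal, endothelial and leukocyte cells, which a pure line should not hold, rose at 250 µM in 3 of 17 cases (2 adjusted over the list alone), with a median of 0.20 and an adjusted p of 0.0491. This call was lost with an estimated correlation (adjusted p = 0.259), with quantile normalization (0.483), array weights (0.0765) or ranks (0.0816), and without control array 2 (0.0786), 150 µM array 3 (0.0511), 250 µM array 1 (0.0623), 250 µM array 3 (0.0750) or 250 µM arrays 2 and 3 (0.110). Dim rows as a whole stood higher on these arrays, by 0.12 to 0.21 in the dimmest of the 4 parts. The lists not called at 250 µM were aryl hydrocarbon receptor targets (adjusted p = 0.766), fatty acid synthesis (0.490), glycolysis and hypoxia (0.135), metallothioneins (0.0872), cytosolic ribosomal proteins (0.0872), apoptosis regulators (0.871), drug conjugation and efflux (0.80) and basal and mesenchymal markers (0.0572). For apoptosis regulators the mean was 0.24 on 250 µM array 1 and -0.18 and -0.32 on the others, and without arrays 2 and 3 the list was called up (median 0.25, adjusted p = 0.0362). Metallothioneins and cytosolic ribosomal proteins were called up with quantile normalization (adjusted p = 0.0369 and 0.00692), with array weights (0.0148 and 0.0298) and without 250 µM array 1 (0.00839 and 0.0219). The ribosomal proteins were also called up among brighter rows (0.00598). Glycolysis and hypoxia genes were called up with quantile normalization (0.0221) and among brighter rows (0.0368), and basal and mesenchymal markers without control array 1 (0.0430), 250 µM array 1 (0.0469) or 250 µM array 2 (0.0475). In drug conjugation and efflux, the median (0.08) and the mean (-0.14) differed in sign. CYP1A1 was at -0.86 ± 0.12 (SE), with log2 signals of 5.16 and 4.30 that both lay below the median of all rows. Further large rises were those of RND1 (3.76 ± 0.27), the aldolase ALDOC (3.13 ± 0.20) and the GTPase GEM (3.00 ± 0.20). Means below the median of all rows on every array, where background signal limits the fold, were those of ATF3 and GEM in control cells and of ASPM, DTL, NDC80 (4.33), RAD51AP1 (4.21), E2F8 (4.43) and BRCA1 (5.03) at 250 µM. In total 8177 of 19310 genes were called, 3812 higher and 4365 lower, and 451 and 1388 of them changed at least 2-fold. Centring arrays on their medians gave 5172 higher and 3931 lower, and the majority also turned with array weights (5844 and 5525), with all rows tested (5228 and 4774) and without 250 µM array 1 (5699 and 5475). The count was 5429 among brighter rows and 5404 without control array 2. Groups did not overlap for 52.4% of genes, where chance gives 10%. Of the 36 lists, 27 were called, 9 up and 18 down, and 4 with an estimated correlation.

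The doses were compared directly as well. From 150 µM to 250 µM, DNA replication genes fell further in 16 of 44 cases (21 with 2 rises adjusted over the list alone), with a median of -0.38 and an adjusted p of 3.93e-06 (adjusted p = 0.390 with an estimated correlation, so that the call was lost). The median was -0.24 with quantile normalization. RRM1, a ribonucleotide reductase subunit, and GINS4 were at -1.17 ± 0.20 and -0.85 ± 0.14 (SE). Both calls were lost without 150 µM array 3 (adjusted p = 0.0509 and 0.0512), and RRM1 was at -0.63 without 250 µM arrays 2 and 3. For mitosis genes, 6 of 39 rose and 7 fell (6 and 7 adjusted over the list alone), with a median of 0.03, a test statistic pointing down and an adjusted p of 0.912. The 250 µM arrays differed in direction, as the list mean of -2.99 on array 1 lay below all 150 µM arrays (-2.69 to -2.57) and the means of -2.45 and -2.37 on arrays 2 and 3 lay above them. Without arrays 2 and 3 the median was -0.35 (adjusted p = 4.30e-07), and without array 1 it was 0.16 (adjusted p = 0.0530). Endoplasmic reticulum chaperones were not called, with a median of -0.03 and a mean of 0.03 that differed in sign (adjusted p = 0.912), but were called up with quantile normalization (0.0399). Oestrogen receptor targets fell in 10 of 24 cases (13 with 1 rise adjusted over the list alone; adjusted p = 4.52e-04, and adjusted p = 0.390 with an estimated correlation), with a median of -0.39 that moved to -0.25 with quantile normalization and to -0.19 without 250 µM arrays 2 and 3. The receptor's corepressor NRIP1 was at -1.07 ± 0.21, and at -0.45 without 250 µM arrays 2 and 3 (adjusted p = 0.0686), and lost its call in 6 alternatives. Among these were omission of 150 µM array 2 (0.0571) or 3 (0.0683) and of 250 µM array 2 (0.0587) or 3 (0.0539). HSPB8 had a log2 fold change of -0.99 ± 0.33 (adjusted p = 0.0569), with a log2 signal of 9.79 on 250 µM array 1, near the 150 µM mean of 9.76, and of 8.29 and 8.21 on the others. It was at 0.03 without arrays 2 and 3, and at -1.51 and called without array 1 (adjusted p = 1.75e-07). NRF2 targets fell in 8 of 19 cases (13 adjusted over the list alone; adjusted p = 3.12e-05, and adjusted p = 0.390 with an estimated correlation), a call lost without 250 µM arrays 2 and 3, where the median went from -0.61 to -0.14 (adjusted p = 0.295). SLC7A11 had the largest fall, -2.51 ± 0.75, but its log2 signal was 11.12 on 250 µM array 1, near the 150 µM mean of 11.21, and 7.70 and 7.27 on the other 250 µM arrays. AKR1C3 was at -1.14 ± 0.32, and at -0.18 without 250 µM arrays 2 and 3, and has close paralogues that probes may also read. p53 targets fell in 9 of 27 cases (11 adjusted over the list alone; adjusted p = 0.00422, and adjusted p = 0.390 with an estimated correlation), with a median of -0.25 and with SPATA18 at -0.97 ± 0.15. This call was also lost with quantile normalization (median -0.10, adjusted p = 0.177), with brighter rows only (0.357), with array weights (0.0599) and without 250 µM array 1 (0.0909). GDF15 had a log2 fold change of -0.98 ± 0.36 (adjusted p = 0.0763), and was at 0.15 without 250 µM arrays 2 and 3 and at -1.54 and called without array 1 (adjusted p = 1.33e-07). Its signal of 12.09 on array 1 lay near the 150 µM mean of 11.94.

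Of 8 repair lists, 6 were called lower at 250 µM than at 150 µM, among them nucleotide excision repair and translesion synthesis, which were not called at 150 µM against control. Each of these 6 calls was lost with an estimated correlation (adjusted p = 0.390 with an estimated correlation). Of 128 repair genes, 37 fell and 3 rose, with a median of -0.26. Homologous recombination fell in 7 of 24 genes (9 adjusted over the list alone; adjusted p = 0.00693), with GEN1 at -1.38 ± 0.29 and RAD50, a break-binding subunit, at -1.22 ± 0.34 (SE). Without 250 µM arrays 2 and 3 these genes were at -0.51 and -0.27, and RAD50 was at -0.79 without array 3. The adjusted p was 0.0126 for the Fanconi anaemia pathway and translesion synthesis, 0.0155 for nucleotide excision repair and the checkpoint and 0.0228 for mismatch repair, and base excision repair (0.0690) and end joining (0.216) were not called, although base excision repair was without 150 µM array 1 (0.0461). Without 250 µM array 1 a single repair list, 1 of 8, was called, and among brighter rows 0 were. The exception without array 1 was translesion synthesis, whose call was lost without arrays 2 and 3 (median -0.09, adjusted p = 0.184). Quantile normalization also ended the calls of nucleotide excision repair (0.155) and mismatch repair (0.0965), and array weights that of mismatch repair (0.0854). Falls were also called for G1/S regulators (adjusted p = 0.0244), fatty acid synthesis (0.0155) and luminal markers (0.0259), each with an adjusted p = 0.390 with an estimated correlation. These 3 calls were lost with quantile normalization (0.124, 0.115 and 0.324), brighter rows only (0.457, 0.451 and 0.452) and without 250 µM array 1 (0.0549, 0.176 and 0.0549). That of fatty acid synthesis was also lost with array weights (0.109). The G1/S call was also lost without 150 µM array 3 (0.0575), and it and the luminal call without 250 µM array 2 (0.0558 and 0.0586) and without arrays 2 and 3 (0.0989 and 0.184). Rises were called for histones (9 of 33 rose and 1 fell, 19 and 1 adjusted over the list alone; adjusted p = 3.93e-06, and adjusted p = 0.470 with an estimated correlation) and interferon genes (7 of 25 rose, 7 adjusted over the list alone; adjusted p = 0.0307, and adjusted p = 0.616 with an estimated correlation). A rise was also called for stromal, endothelial and leukocyte markers (1 of 17 rose, 0 adjusted over the list alone; adjusted p = 0.0158, and adjusted p = 0.390 with an estimated correlation). H4C4 and H2BC14 were the histones with the largest rises, 1.58 ± 0.42 and 1.10 ± 0.19, and at 0.29 and 0.61 without 250 µM arrays 2 and 3. The histone call was lost without these arrays (median 0.08, adjusted p = 0.727), and that of the stromal, endothelial and leukocyte markers with quantile normalization (0.315), array weights (0.0507) and without 250 µM array 1 (0.0549). The interferon rise rested on 250 µM array 1, and without it the list's median was -0.14 with an adjusted p of 0.488. The call was also lost with array weights, where the median turned to -0.04 (adjusted p = 0.806), and with ranks (0.0522). Of these 16 list calls, none held with an estimated correlation, where adjusted p ran from 0.390 upwards, and only DNA replication and oestrogen receptor targets were called in all other alternatives.

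Single genes with large rises from 150 µM to 250 µM were WNK1 (2.38 ± 0.39, SE), SNX31 (2.08 ± 0.39), IQCN (1.96 ± 0.53), RNF151 (1.92 ± 0.51), RHOH (1.84 ± 0.37) and CHCT1 (1.77 ± 0.34). A brighter row of WNK1, a kinase of ion transport, had a log2 fold change of 0.03 ± 0.10, so that the rows of this gene disagreed. Large falls besides that of SLC7A11 were those of the lipid transporter ABCA12 (-2.37 ± 0.57), HCAR3 (-2.34 ± 0.51), DAPP1 (-1.96 ± 0.44), COXFA4L3 (-1.94 ± 0.59) and PSD3 (-1.88 ± 0.46). Most of these values average 250 µM arrays that differed. IQCN had a log2 signal of 6.72 on array 1, near the 150 µM mean of 6.46, and of 9.28 on both others, and COXFA4L3 was at 7.97 on array 1 (150 µM mean 8.03) and at 5.38 and 4.91 on the others. Without array 1, IQCN and RNF151 were at 2.82 and 2.73 and ABCA12, COXFA4L3, DAPP1 and PSD3 at -3.29, -2.88, -2.65 and -2.59. Without arrays 2 and 3 they were at 0.26 and 0.29 and at -0.53, -0.05, -0.59 and -0.46, and HCAR3 was at -1.53 without array 3. SNX31, RHOH, CHCT1 and HCAR3 were at 0.89, 0.69, 0.78 and -1.38 without arrays 2 and 3. The called row of WNK1 had a log2 signal of 6.44 on array 1 and of 8.15 and 8.27 on the others, against a 150 µM mean of 5.24. At 150 µM the means of SNX31 (4.44), RHOH (4.19), CHCT1 (4.55), H2BC14 and this row of WNK1 lay below the median of all rows. Of 21 named genes called in this comparison, 19 lost the call in at least 1 alternative, all but WNK1 and SPATA18, and the called row of WNK1 was too dim to be tested among brighter rows. In total 3338 genes were called, 1147 higher and 2191 lower, and groups did not overlap for 34.3% of genes, where chance gives 10%. When only these 6 arrays were fitted, without the spread of the control arrays, 296 were called, and array weights gave 8137. The count was 8786 without 250 µM array 1, 408 and 568 without 250 µM arrays 2 and 3, 1148, 362 and 161 without 150 µM arrays 1, 2 and 3, and 1580, 1932 and 1847 without control arrays 1, 2 and 3.

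**Figure D3:**
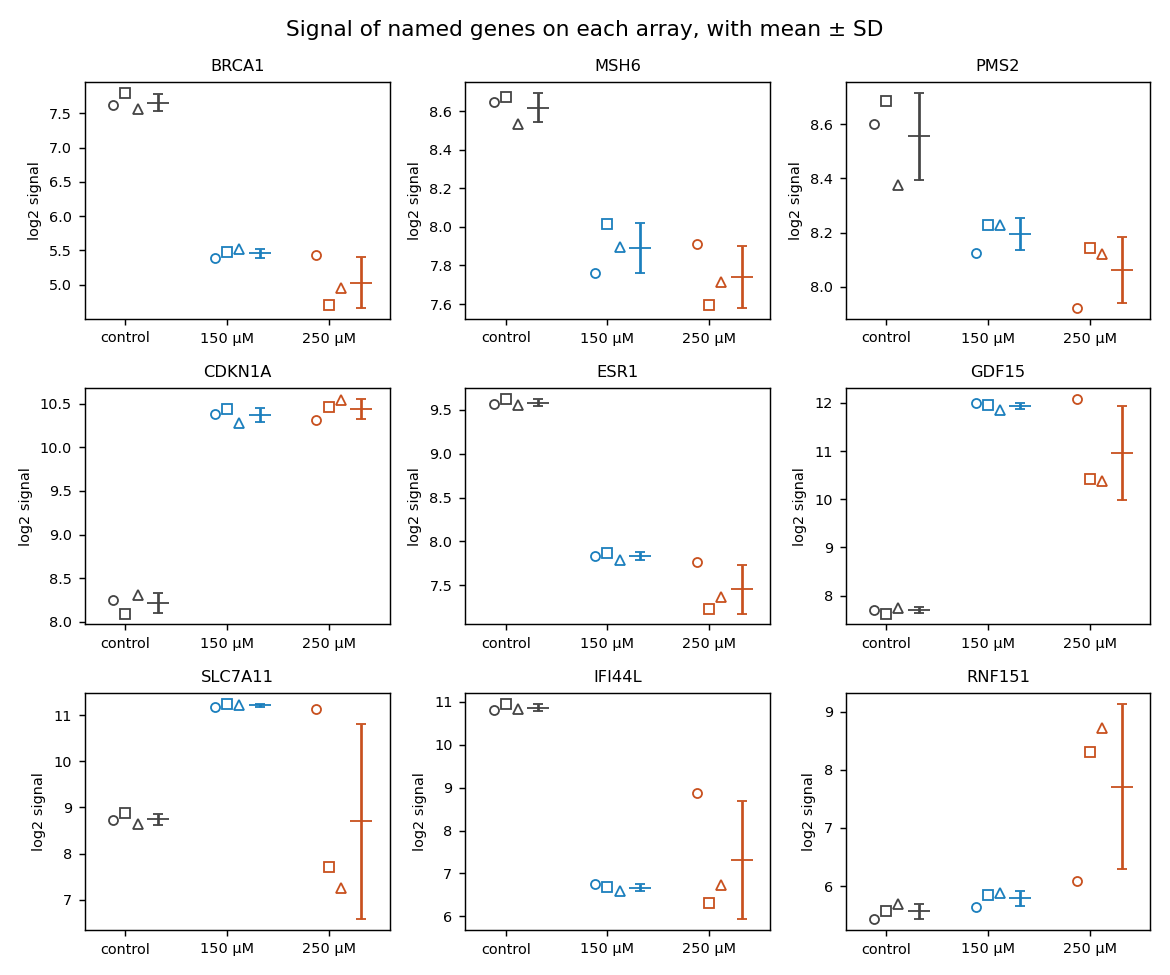
Log2 signal of 9 named genes on each array, by group, with symbols for replicate numbers 1 (circle), 2 (square) and 3 (triangle) and the mean ± SD of each group beside them; each panel has its own vertical scale. BRCA1 lies at 7.66 in control cells and at 5.46 and 5.03 at the doses, whereas SLC7A11, IFI44L and RNF151 at 250 µM differ between the first array and the other two.

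The changes at the doses were set against each other. The log2 fold changes had the same sign for 73.5% of genes, where simulated unchanged groups set against the same controls gave 66.7%. Across genes, which are not independent replicates, the log2 fold changes at 150 µM and 250 µM correlated at r = 0.777 (Spearman's rho 0.664), where the simulation gave 0.50 (rho 0.475). The covariance was 0.249 against 0.0124 in the simulation, which leaves 0.237 beyond what sharing the controls gave there. In total 3363 genes were called at both doses in the same direction, 1328 higher and 2035 lower. Independent lists of these sizes would share 403.1 and 541.4, and simulated unchanged groups shared 0.01 on average. No gene was changed in that simulation, so few could be called in it. It therefore cannot show how much sharing the controls adds to the overlap or the correlation among changed genes. The 3 controls cannot be split with 2 arrays on each side, so part of the correlation, and of the excess in shared calls over independent lists, may come from sharing them. Opposite directions were called for 18 genes, of which 17 rose at 150 µM and fell at 250 µM. Among these, PAM, an amidating enzyme of peptide hormones, was at 0.82 ± 0.15 and -0.50 ± 0.15 (SE), and ALDH7A1, an aldehyde dehydrogenase, at 0.52 ± 0.13 and -0.62 ± 0.13. Others lay near the threshold at both doses, such as EFL1 (adjusted p = 0.0413 and 0.0399 from limma) and ZFP90 (0.0384 and 0.0487). None of the 18 genes was followed through the alternatives. An F-test of any difference among the 3 groups called 8688 of 19310 genes.

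**Figure D4:**
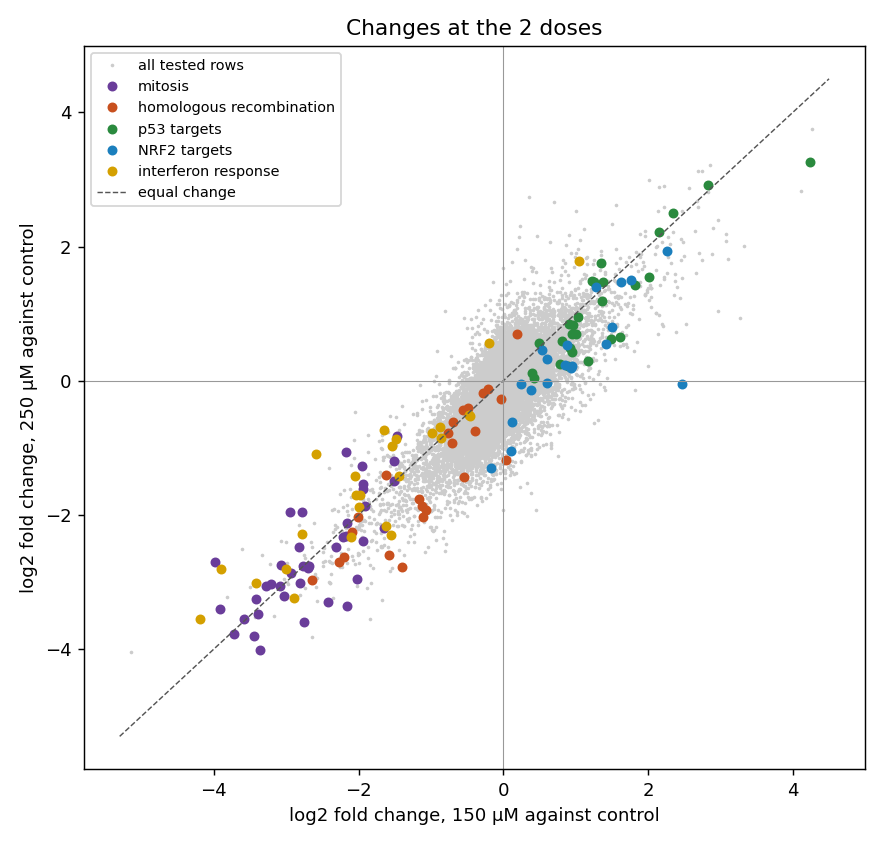
Log2 fold change of each tested gene at 150 µM (horizontal) and 250 µM (vertical) against the same controls, with 5 gene lists coloured and a dashed line where the changes are equal. Mitosis, homologous recombination and interferon genes lie mostly low at both doses and p53 targets high at both, and across all genes r was 0.777.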

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

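The tests of array scaling, of the repair lists tied to replication, and of the first 250 µM array as a 150 µM culture, over all genes and then over repair genes, were chosen after the result was seen. Calls outside the tested rows were counted among 9559 rows with several gene symbols or none, with p-values from limma adjusted over all rows of the table. Of these rows, 623 were called at 150 µM, 2312 at 250 µM (1738 higher and 574 lower) and 746 between the doses. These were smaller shares than among the 19310 tested rows, adjusted among themselves, of which 4437, 8177 and 3338 were called. No explanation was tested for these counts. Genes called in opposite directions at the doses numbered 18, a difference between the dose groups. The direct comparison of the doses uses the same arrays and fit, and no independent test of these genes was available.

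The first 250 µM array lay nearer the 150 µM arrays than the other 250 µM arrays. Its root mean square log2 distance from the 150 µM mean, corrected for the number of arrays averaged, was 0.245, against 0.401 from the other 250 µM arrays. Its distance from the 150 µM mean was 1.59 times the largest among the 150 µM arrays, which argues against a culture like those 3 under a 250 µM label. The limit for this ratio was set after the result was seen, and those 3 arrays lay close together (0.150 to 0.154). The array lay 0.21 of the way from the 150 µM mean to the other 250 µM arrays. More than 1 log2 unit separated it from the 150 µM mean in 95 rows and from the mean of the other 250 µM arrays in 1010. Over the repair genes alone the array lay 1.26 ranges of the 150 µM arrays away, which does not decide. Quantile normalization left the distance to the other 250 µM arrays at 1.02 times its value, which argues against their narrower signal range as the cause. A difference in exposure stays open, although mitosis genes on the first array (-2.99) did not lie between the 150 µM arrays and the other 250 µM arrays, and no biological explanation was tested.

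NRF2 targets and interferon genes differed between the 250 µM arrays, by 0.86 and 1.32 log2 units in the mean between the first and the others, a difference that is not between groups of the design, and mitosis genes by -0.58, with the first array (-2.99) below both the 150 µM arrays and the other 250 µM arrays. After quantile normalization the NRF2 gap was 0.85, which argues against the narrower signal range. The NRF2 and interferon gaps lay outside the middle 95% of 10000 random lists matched on mean expression (-0.05 to 0.39 and -0.05 to 0.37). The gaps were thus larger than those of genes of like brightness drawn singly. These lists were taken up because they stood out between these arrays, and genes drawn singly carry no co-expression. The range is therefore too narrow to exclude a change that follows brightness. A difference in exposure, in cell state or in sample handling between the cultures stays open, and none of these was tested.

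Many, but not all, DNA repair genes fell at both doses. Of 128 measured, 56 fell, 9 rose and 63 did not pass at 150 µM, and 85 fell, 7 rose and 36 did not pass at 250 µM. Nucleotide excision repair was called at neither dose, and translesion synthesis was not called at 150 µM. With an estimated correlation, 2 and 1 of the 8 repair lists stayed called at 150 µM and 250 µM. Array scaling is argued against, since with quantile normalization the pooled repair median stayed 0.37 and 0.60 log2 units below that of all genes (-0.37 and -0.60). A candidate explanation is fewer dividing cells. The 61 genes of the mismatch repair, homologous recombination, Fanconi anaemia and checkpoint lists had a median below that of 67 other repair genes (difference -0.52 at 150 µM and -0.60 at 250 µM), but this split was chosen after the medians of the lists were seen, so that it cannot support the explanation. Fewer dividing cells and a direct action on these genes cannot be told apart here, and both stay open beside dose. By the protocol, ethanol was 0.03% in control and 150 µM cultures and 0.3% at 250 µM. With the source name's 0.3% for the control, ethanol differed from control at 150 µM only. Repair genes fell at both doses, 56 and 85 of 128, which argues against ethanol as the cause of both falls. A contribution of vehicle at 250 µM, or at 150 µM by the source name, stays open.

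Chance was tested by regrouping the arrays. For each 3 against 3 comparison, 1 of 10 splits, the real split, gave as many genes or lists, and 10 splits are too few for a share under 0.05. The genes called were 4437, 8177 and 3338 in the real splits at 150 µM, at 250 µM and between the doses, and 0 was the highest count of the other splits in each. The lists called were 24, 27 and 16, and the highest of the other splits were 22, 21 and 14. These other splits mix the compared groups and keep part of the difference, which also widens the spread within each mixed group. Few genes could be called in them for that reason alone, so the counts of 0 are no evidence for the real splits. Up to 22, 21 and 14 lists were nevertheless called in splits that called no gene, so the list counts hardly separate the real splits from the others. For the F-test, 1 of 100 drawn splits of the 9 arrays, the real split, gave as many as the real 8688 genes, a share under 0.05. A random grouping is thus unlikely there, but a culture or handling difference that follows the groups is not excluded. The highest of the other splits gave 5801.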

How the results depend on the processing

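One alternative, leaving out 250 µM arrays 2 and 3 together, was chosen after seeing the data. Counts moved by over 1.5 times as follows, and the cause was not tested unless given. With array weights, 7362 genes were called at 150 µM, 8137 between the doses and 5187 at both doses in the same direction. This setting gave 250 µM array 1 the lowest weight (0.141), and its 8137 lies near the 8786 without that array. Fitting only the groups compared gave 6799 at 150 µM and 296 between the doses. Among brighter rows, with fewer genes tested, 5429 genes were called at 250 µM, and 6 lists and 0 repair lists between the doses. An estimated correlation left 10, 4 and 0 lists and 2, 1 and 0 repair lists at 150 µM, at 250 µM and between the doses. Without 250 µM arrays 2 and 3, with the lone array assumed to vary like the other groups, the gene counts were 6799, 5191 and 731. There the apoptosis list changed direction at 250 µM (median 0.25, adjusted p = 0.0362), as did HSPB8 (0.030) and GDF15 (0.15) between the doses. Spearman's correlation of the doses was 0.664, against Pearson's 0.777.

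Leaving out each array in turn, 3122 to 6573 genes were called at 150 µM, 5404 to 11174 at 250 µM, 161 to 8786 between the doses, 6123 to 12225 by the F-test and 2305 to 4704 at both doses in the same direction, and the dose correlation ran from 0.683 to 0.818. Lists called ran from 20 to 24, from 25 to 28 and from 7 to 18, and repair lists from 5 to 6, at 7 throughout and from 1 to 7. Between the doses, the median of the interferon list ran from -0.14, without 250 µM array 1, to 0.50. For the apoptosis list at 250 µM it ran from -0.20 to 0.03, and between the doses HSPB8 ran from -1.51 to -0.72 and GDF15 from -1.54 to -0.69.

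With the replicate number as a block, 2087 genes were called between the doses, and no other count moved by over 1.5 times. Arrays with the same number did not deviate together (r from -0.20 to 0.09), and 2 of 9 arrays correlated best with their own number, so that the numbers are not read as pairs. Leaving aside the estimated correlation, 23 of 24 named genes kept their call at 150 µM in all alternatives that gave them a value, 27 of 28 at 250 µM and 2 of 21 between the doses. Of the genes that kept it, 4, 5 and 1 were too dim to have a value among brighter rows. Apart from the fixed panel, named genes were picked for large changes on these same arrays. Their kept calls therefore do not extend to all called genes. For lists, 19 of 24, 18 of 27 and 2 of 16 kept their call. Fold changes of dim rows are limited by background signal.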

Other observations

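The genes here, of stress and survival, were chosen after their values were seen, and limma tested each between the doses. PPP1R15A, which restores translation after stress, was at 2.15 and 2.88 at 150 µM and 250 µM, and rose between the doses by 0.73 ± 0.14 (SE, adjusted p = 0.0125). That call was lost when only these groups were fitted (0.0553), without 150 µM array 2 (0.0540) or 3 (0.0644), without 250 µM array 2 (0.0501) and without 250 µM arrays 2 and 3 (log2 fold change 0.44, adjusted p = 0.0888). ATF4 stress response genes as a list had means of 0.87 and 0.64 and no call between the doses (adjusted p = 0.131), but were called lower without 250 µM array 3 (0.0451) and without arrays 2 and 3 (0.00710).

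BCL2, which restrains cell death, was at -0.38 (adjusted p = 0.447) and -1.41 (adjusted p = 0.00374), and at -1.03 ± 0.30 between the doses (adjusted p = 0.0398). Its log2 signal was 8.19 on 250 µM array 1, near the 150 µM mean of 8.30, and 6.91 and 6.72 on the others. Without arrays 2 and 3 it was at -0.49 at 250 µM and at -0.11 between the doses (adjusted p = 0.656), and the call between the doses was lost in 11 alternatives, among them omission of any array but 250 µM array 1. At 150 µM it was called in 4 alternatives, among them omission of 250 µM array 1 (adjusted p = 0.00650). BCL2L11, which promotes cell death, was at 0.96 and 0.71, with no call between the doses (-0.25 ± 0.14, adjusted p = 0.225), except with array weights (0.0184) and without 250 µM array 1 (-0.41, adjusted p = 0.00789), and at 0.08 without arrays 2 and 3.

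IRF1 rose at both doses, by 1.05 and 1.79, where most other interferon genes fell. Between the doses it was at 0.75 ± 0.21 (adjusted p = 0.0355), a call lost in 10 alternatives, among them omission of any array but 250 µM array 1, and at 0.19 without 250 µM arrays 2 and 3 (adjusted p = 0.517). NEU1, a lysosomal sialidase with several rows on the array, was at 2.48 and 2.53 in its brightest row, and at 0.05 ± 0.15 between the doses (adjusted p = 0.830), with values from -0.34 to 0.25 over the alternatives and no call in any.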
